A study of Mus musculus with 40 samples.

How the data were processed

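The deposited values were raw read counts per gene symbol from the authors, 1 file per library, with 24499 genes and 5 closing tallies of reads that were counted on no gene. The tallies were used for quality measures only. Per the labels' protocols, libraries came from total liver RNA with the TruSeq mRNA kit, and the submitters' processing notes name mm10, GSNAP and DESeq2 1.12.3 without their roles. The counting program, its annotation and its strand setting are not given in the sources used here. All reads tallied per library ran from 13886900 to 56452100 (median 29690600), of which 41.0% to 51.8% were counted on genes, 20.1% to 28.2% on no feature, 17.1% to 28.7% aligned to more than 1 place and 4.80% to 9.72% did not align. Between 16010 and 17567 genes had at least 1 read per library. In GENCODE vM21, 23636 of the 24499 symbols matched 1 gene, as did 13946 of the 14355 tested. Reads that align to more than 1 place were not counted, so members of near-identical families (Mup, Saa1 and Saa2, Gstm, Cyp2a, Cyp2b, Cyp2c and Cyp4a copies) have uncertain values.

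Group and replicate came from the labels alone, and animals are taken as separate because each label carries its own number. All 40 libraries entered 1 fit with 1 coefficient for each of the 8 groups in edgeR 4.0.16 (R 4.3.3). It used TMM factors, the filterByExpr default by group (14355 genes kept), robust quasi-likelihood dispersion, the two-sided quasi-likelihood F test and Benjamini-Hochberg adjustment, with a call at an adjusted p under 0.05. Interactions were contrasts of the same fit. CPM values used library totals scaled by TMM factors and no pseudocount, and plots used log2 of CPM plus 1. The gene lists were tested by camera (limma 3.58.1) at an inter-gene correlation of 0.01, and again with a correlation estimated for each list. They were bile duct epithelium, extracellular matrix, stellate cells and myofibroblasts, Kupffer cells, recruited macrophages, neutrophils, T and NK cells, B and plasma cells, sinusoidal endothelium, red blood cells, pancreas and fat, hepatocyte identity, pericentral hepatocyte, periportal hepatocyte, heme synthesis and breakdown, NRF2 targets, CAR and PXR targets, bile acid synthesis, bile acid and bile transport, fatty acid synthesis, cholesterol synthesis, fatty acid oxidation and PPAR-alpha targets, lipid droplets, alcohol and acetaldehyde metabolism, unfolded protein and integrated stress response, interferon response, acute phase response, cytokines and chemokines, cell cycle, p53 targets, keratin aggregate components, fetal liver genes, male-biased liver genes, female-biased liver genes, circadian clock. Lists such as bile duct epithelium, stellate cells, macrophages, neutrophils and pancreas and fat mark other cell types that a liver sample can hold. Members missing from the files or under the filter were left out of a list.

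The comparisons, lists, named-gene rule and alternatives were chosen before the data were examined, except where the text says that a setting was chosen after seeing the data. Named genes were the 5 largest increases and 5 largest decreases of each main comparison, and 3 of each in the others, by log2 fold change. They needed an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and, for comparisons of 2 groups, no overlap between the groups' libraries. Predicted genes, clone names and Mup genes were passed over. Up to 4 members with the smallest adjusted p of each described list, members called against the list, and a fixed panel of 47 liver genes were added, and the text names part of these.

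Alternatives were median-ratio size factors (RLE), no low-count filter, a stricter filter (at least 1 CPM in at least 4 libraries and a mean count of at least 10), sequencing lane as a term, robust estimation off, only the libraries of the groups compared, DESeq2 1.42.0, and each library left out in turn. Sequencing lane, read from the deposited names, had 6 levels. Control 0D lay in lanes 1 to 4 and DDC 0D in lanes 3 to 6, so lane and group overlap in part there. The flow cell is not given in the sources used here, so a lane number can stand for more than 1 run. Added after seeing the data were fits without 7 libraries over 1000 CPM of 8 pancreatic enzyme transcripts, with log2 of that CPM as a term, and with a clock score (Arntl, Npas2 and Clock minus Dbp, Tef, Hlf and Per3) as a term. Sequence reads, sex-linked genes and allele differences were not analysed here. The results of a single named gene are not reported here, and the alternatives have no entries of it.

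In a self-test, counts simulated with fitted dispersions had 200 genes changed by known folds of 1.5, 2 and 4 in each comparison and no other group differences. Recovery at those folds was 37.9%, 76.1% and 90.9% for DDC 0D against Control 0D, 59.1%, 80.3% and 95.5% for DDC+Cont against Control 28D, 19.4%, 57.6% and 81.2% for the DDC interaction and 47.0%, 76.1% and 95.4% for HFD against Control 28D. It was 53.0%, 78.5% and 97.0% for EtOH against HFD, 55.4%, 80.3% and 98.4% for DDC+HFD against DDC+Cont, 57.6%, 85.1% and 95.4% for DDC+EtOH against DDC+HFD and 28.4%, 50.7% and 92.3% for the alcohol interaction. It was 46.2%, 80.0% and 93.9% for DDC+EtOH against EtOH, 49.3%, 83.3% and 97.0% for DDC+HFD against HFD, 48.4%, 77.6% and 98.5% for DDC+EtOH against Control 28D and 59.7%, 77.3% and 96.9% for Control 28D against Control 0D. No changed gene was called in the wrong direction, and unchanged genes made up 1.94% to 7.65% of the calls. An extracellular matrix list raised 1.5-fold was called by camera, with 1 other list called in DDC 0D against Control 0D and 0 in DDC+EtOH against DDC+HFD. Simulated effects with no shared change had a correlation across genes of -0.0417 for the 2 ethanol contrasts and 0.0426 for the 2 DDC contrasts.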

Results

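RNA from livers of adult male C57BL/6 mice was read by messenger RNA sequencing in 40 libraries, taken as 1 per animal because each label carries its own number. Per the labels' protocols, mice first received a diet marked BD or a diet with 3,5-diethoxycarbonyl-1,4-dihydrocollidine (DDC, 0.05% w/w), a porphyrinogenic compound given to induce chronic liver fibrosis. A second treatment followed in most groups: BD, HFD, or HFD with ethanol through a gastric feeding tube, up to 27 g per kg per day for up to 28 days. The labels do not spell out BD and HFD. The groups without a second treatment were Control 0D (n = 4) and DDC 0D (n = 4). The groups with one were Control 28D (n = 5), HFD (n = 6) and EtOH (n = 4) after BD, and DDC+Cont (n = 5), DDC+HFD (n = 6) and DDC+EtOH (n = 6) after DDC. Values were the deposited raw read counts per gene, given below in CPM, the usual unit of counts scaled to the library total, with TMM factors, as mean ± SD over the n of the group. Reads counted on genes ran from 7197940 to 26398100 per library, with a median of 13653500. Each gene was compared with edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over 14355 tested genes, and a log2 fold change is given ± SE. Each fixed gene list was compared with all other genes by camera, adjusted over the 35 lists of a comparison. In GENCODE vM21 (GRCm38/mm10), the plotted genes lie at chromosome 11, 94936224 to 94953042 (Col1a1), chromosome 5, 104435118 to 104441050 (Spp1), chromosome 6, 49036546 to 49070929 (Gpnmb), chromosome 8, 107388225 to 107403206 (Nqo1), chromosome 7, 26307169 to 26315088 (Cyp2a4) and chromosome 3, 98618634 to 98630252 (Hsd3b5), all protein coding.

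DDC feeding alone (DDC 0D against Control 0D) raised genes of bile duct cells, scar matrix and macrophages. Spp1, osteopontin, a secreted phosphoprotein of ductular cells, stood at 913 ± 56.8 CPM against 35.1 ± 2.83 CPM (n = 4 and 4), a log2 fold change of 4.70 ± 0.24. Gpnmb, a glycoprotein of lipid-laden macrophages, rose from 0.228 ± 0.205 CPM to 90.5 ± 14.3 CPM (log2 fold change 8.63 ± 0.91), and Col1a1, a chain of fibrillar type I collagen, reached 49.1 ± 12.9 CPM against 2.01 ± 0.569 CPM (log2 fold change 4.60 ± 0.56). Among the genes with the largest increases were Cxcl5, a neutrophil-attracting chemokine (log2 fold change 9.39 ± 1.02), Slc7a11, the cystine importer that feeds glutathione synthesis (8.64 ± 1.28), Lrtm2 (8.33 ± 0.81) and Sprr1a, a cornified-envelope protein, at least 450-fold higher because Control 0D held no count of it (floor of 3 counts over the group). In the list of bile duct epithelium, 17 of 19 measured genes rose (17 adjusted over the list alone), median log2 fold change 3.53, camera adjusted p = 1.60e-13, or 0.0158 with an estimated correlation. Its members included the ductular adhesion molecule Epcam (4.04 ± 0.26), the tetraspanin Tspan8 (4.55 ± 0.32) and the biliary keratins Krt19 (3.15 ± 0.36) and Krt7 (3.84 ± 0.36). In the extracellular matrix list, 27 of 28 measured genes rose (27 adjusted over the list alone), median log2 fold change 2.52, camera adjusted p = 3.10e-25, or 0.0238 with an estimated correlation. They included Col5a2, a fibril-forming collagen (3.67 ± 0.26), the microfibril protein Fbn1 (2.72 ± 0.18), the proteoglycan Lum (3.08 ± 0.24), the basement membrane collagen Col4a1 (1.69 ± 0.13) and Timp1, an inhibitor of matrix proteases (7.60 ± 0.63).

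Leukocyte and stress genes moved in the same animals. Of the recruited macrophage list, 14 of 16 measured genes rose (15 adjusted over the list alone), median log2 fold change 3.82, camera adjusted p = 2.08e-12, or 0.0370 with an estimated correlation. The fractalkine receptor Cx3cr1 stood at 5.04 ± 0.29, the lipid receptor Trem2 at 5.61 ± 0.48 and the tetraspanin Cd9 at 3.04 ± 0.19. Of the cytokines and chemokines, 18 of 21 measured genes rose (19 adjusted over the list alone), median log2 fold change 2.72, camera adjusted p = 8.40e-09, or 0.0895 with an estimated correlation. Among them were the monocyte chemokine Ccl2 (4.81 ± 0.52) and the adhesion molecule Vcam1 (3.37 ± 0.22). Of the NRF2 targets, the genes driven by the oxidant-sensing factor NRF2, 18 of 23 measured genes rose and 1 fell (18 and 1 adjusted over the list alone), median log2 fold change 1.40, camera adjusted p = 1.70e-06, or 0.129 with an estimated correlation. Gpx2, a glutathione peroxidase (7.57 ± 0.67), and Nqo1, a quinone reductase (2.40 ± 0.28), were higher, while Me1, malic enzyme, fell (-0.98 ± 0.37), a call lost with sequencing lane as a term (adjusted p = 0.110) and without Control 0D replicate 1 or DDC 0D replicate 6 or 8 (adjusted p = 0.0579, 0.0559 and 0.0810). In the cell cycle list, 25 of 28 measured genes rose and 1 fell (26 and 1 adjusted over the list alone), median log2 fold change 2.30, camera adjusted p = 1.06e-05, or 0.388 with an estimated correlation. The G1 cyclin Ccnd1 stood at 2.91 ± 0.29, the mitotic kinase Cdk1 at 3.18 ± 0.46 and the thymidine kinase Tk1 at -0.90 ± 0.19. Of the keratin aggregate components, 4 of 8 measured genes rose and 1 fell (4 and 1 adjusted over the list alone), median log2 fold change 0.30, camera adjusted p = 0.0288, or 0.129 with an estimated correlation. Without a low-count filter that call was lost (adjusted p = 0.122), and the member that fell was Nbr1 (-0.45 ± 0.078). The hepatocyte keratins Krt8 (2.69 ± 0.17) and Krt18 (2.24 ± 0.19), the usual substrate of DDC-induced aggregates, both rose.

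Genes of mature hepatocytes fell. Hsd3b5, a male-specific steroid dehydrogenase, went from 264 ± 46.2 CPM to 0.127 ± 0.0949 CPM (log2 fold change -11.15 ± 1.23), and Elovl3, a fatty acid elongase, from 950 ± 175 CPM to 2.27 ± 1.02 CPM (-8.73 ± 0.95). The other largest decreases were those of the serpin pseudogene Serpina4-ps1 (-8.72 ± 1.75), the sulfotransferase Sult2a8 (-7.30 ± 0.55) and the homeobox factor Pitx3, at least 369-fold lower because DDC 0D held no count of it. Of the male-biased liver genes, 14 of 14 measured genes fell (14 adjusted over the list alone), median log2 fold change -3.21, camera adjusted p = 1.43e-09, or 0.0792 with an estimated correlation. The organic anion carrier Slco1a1 stood at -6.07 ± 0.65. Of the hepatocyte identity list, 19 of 20 measured genes fell (19 adjusted over the list alone), median log2 fold change -0.74, camera adjusted p = 2.83e-08, or 0.0370 with an estimated correlation. They included transthyretin, Ttr (-1.41 ± 0.14), and the tyrosine-degrading dioxygenase Hpd (-1.46 ± 0.16). Of the bile acid synthesis list, 9 of 14 measured genes fell (10 adjusted over the list alone), median log2 fold change -1.05, camera adjusted p = 1.81e-07, or 0.0370 with an estimated correlation. The oxysterol hydroxylase Cyp7b1 stood at -3.52 ± 0.36, while Cyp7a1, the rate-limiting enzyme of that route, stood at -0.07 ± 0.53 (adjusted p = 0.927 by edgeR's quasi-likelihood test). Of the fatty acid oxidation list, 18 of 23 measured genes fell (18 adjusted over the list alone), median log2 fold change -0.91, camera adjusted p = 2.19e-08, or 0.136 with an estimated correlation. Of the pericentral genes, 1 of 16 measured genes rose and 10 fell (1 and 11 adjusted over the list alone), median log2 fold change -0.90, camera adjusted p = 5.56e-04, or 0.203 with an estimated correlation. The ethanol-metabolizing Cyp2e1 stood at -2.41 ± 0.25 and glutamine synthetase, Glul, at -1.42 ± 0.20, while the amino acid carrier Slc1a4 rose (1.66 ± 0.49). Periportal genes included Cyp2f2 (-2.39 ± 0.20) and, as the riser, Hsd17b13 (0.53 ± 0.20): 1 of 15 measured genes rose and 8 fell (1 and 8 adjusted over the list alone), median log2 fold change -0.86, camera adjusted p = 6.47e-04, or 0.289 with an estimated correlation. The Hsd17b13 call was lost with no low-count filter and without Control 0D replicate 3 (adjusted p = 0.0538 and 0.0529). In all, 3954 genes were higher and 3515 lower. The clock score, the mean log2 CPM of 3 core clock genes minus that of 4 output genes, was -1.57 ± 0.869 against 1.90 ± 0.842. That difference did not pass adjustment (exact permutation test, p = 0.0286, the smallest that 4 against 4 can give, adjusted p = 0.0571 over 6 comparisons). Library measures also stood apart between these groups: the TMM factor was 1.22 to 1.23 in DDC 0D against 0.942 to 0.989 in Control 0D. Reads aligned to more than 1 place made up 17.1% to 18.5% against 23.9% to 25.7%, reads on no feature 23.8% to 28.2% against 22.4% to 23.2%, and reads on genes 47.3% to 51.8% against 44.7% to 46.4%.

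**Figure D1:**
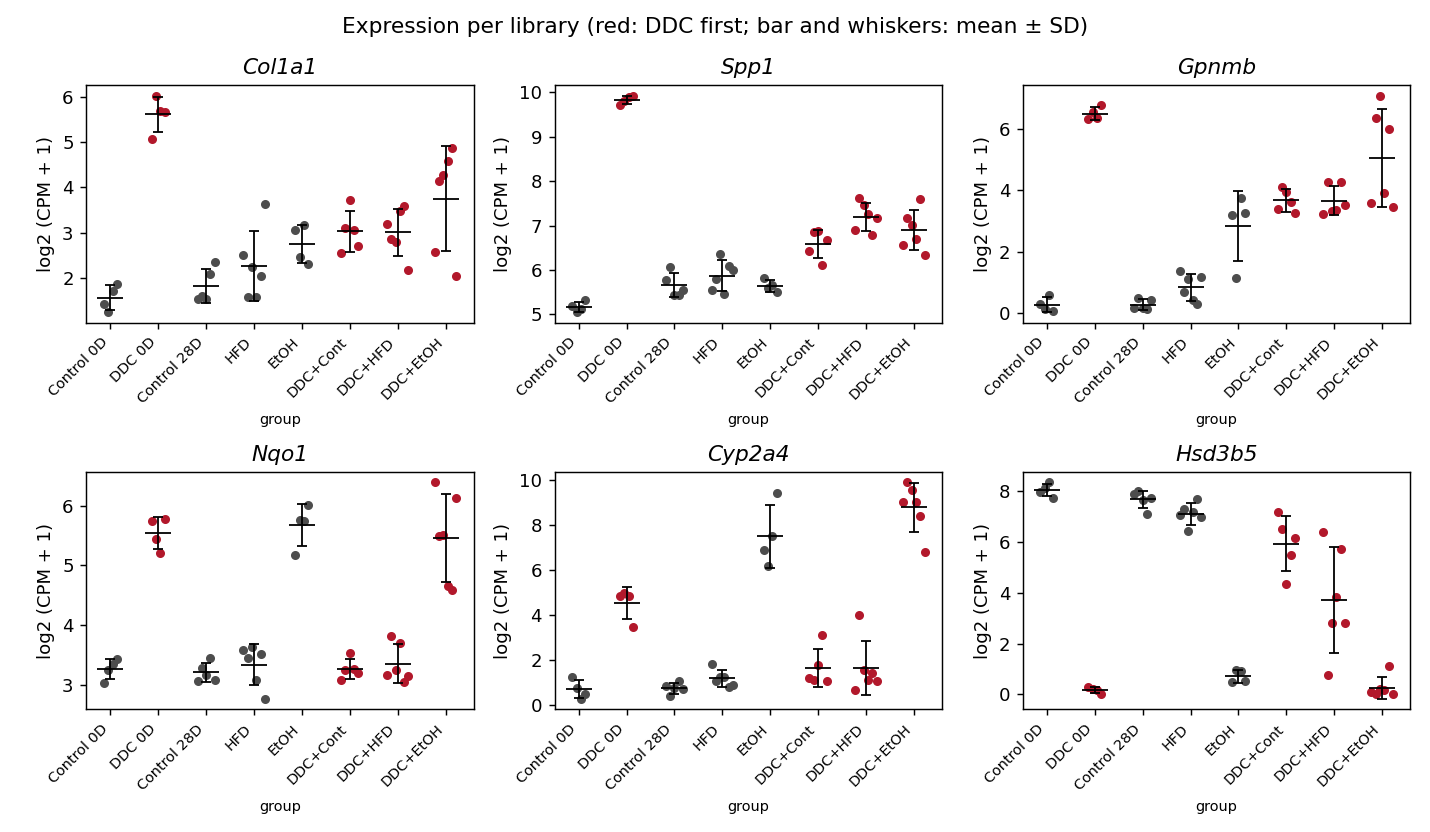
Level of 6 genes in each of the 40 libraries as log2 of CPM plus 1, by group, with bars at group means, whiskers of 1 SD and red for groups that received DDC first. Spp1 averaged 913 CPM in DDC 0D and 35.1 CPM in Control 0D, and Nqo1 51.0 CPM in EtOH and 9.38 CPM in HFD.

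After DDC was followed by the control second treatment (DDC+Cont against Control 28D), part of the ductular, matrix and macrophage signal was still measurable. Gpnmb was 12.1 ± 3.29 CPM against 0.220 ± 0.152 CPM (n = 5 and 5), a log2 fold change of 5.83 ± 0.88, and Spp1 was 97.1 ± 20.5 CPM against 50.2 ± 9.87 CPM (0.95 ± 0.19). Ntrk2, the receptor of brain-derived neurotrophic factor (4.40 ± 0.47), Lrtm2 (3.92 ± 0.52), the epithelial membrane protein Emp1 (2.14 ± 0.28) and the caspase Casp12 (1.97 ± 0.29) rose. The largest decreases were in Moxd1, a copper monooxygenase (-3.48 ± 0.85), Trhde, a peptidase that degrades thyrotropin-releasing hormone (-2.43 ± 0.40), Chic1 (-1.43 ± 0.21), the calpain Capn8 (-1.44 ± 0.32) and the complement regulator Susd4 (-1.43 ± 0.28). Of the bile duct list, 4 of 19 measured genes rose (10 adjusted over the list alone), median log2 fold change 0.84, camera adjusted p = 9.40e-13, or 0.0174 with an estimated correlation. Epcam stood at 1.43 ± 0.25. Of the extracellular matrix list, 8 of 28 measured genes rose (16 adjusted over the list alone), median log2 fold change 0.85, camera adjusted p = 9.47e-22, or 0.0286 with an estimated correlation. Among them were the matricellular thrombospondin Thbs2 (1.32 ± 0.18), the microfibrillar collagen Col6a3 (1.36 ± 0.23) and Lum (1.27 ± 0.21). Col1a1 stood at 1.53 ± 0.49 (adjusted p = 0.121). Of the stellate cell and myofibroblast list, 3 of 15 measured genes rose (6 adjusted over the list alone), median log2 fold change 0.16, camera adjusted p = 7.89e-07, or 0.0174 with an estimated correlation. Members were the growth factor receptors Pdgfrb (0.80 ± 0.12) and Pdgfra (0.92 ± 0.15) and the stellate cell globin Cygb (0.87 ± 0.14). Of the recruited macrophages, 3 of 16 measured genes rose (9 adjusted over the list alone), median log2 fold change 0.94, camera adjusted p = 7.93e-14, or 0.0286 with an estimated correlation. Trem2 stood at 2.75 ± 0.44. Of the T and NK cell list, 2 of 12 measured genes rose (4 adjusted over the list alone), median log2 fold change 0.69, camera adjusted p = 1.42e-04, or 0.111 with an estimated correlation. Under the stricter low-count filter that call was lost (adjusted p = 0.0522).

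DDC+Cont replicate 24 held 2612 CPM of pancreatic enzyme transcripts, and no Control 28D library held over 1000 CPM. The pancreas and fat list was called beside the ductular one (median log2 fold change 6.89, camera adjusted p = 0.0426, or 0.572 with an estimated correlation), with a median of 0.89 without DDC+Cont replicate 24 (adjusted p = 0.720). That call was also lost without Control 28D replicate 9, 10, 11 or 13 (adjusted p from 0.0551 to 0.164), under the stricter low-count filter (0.108) and with only these groups in the fit (0.110). It was lost too without the pancreas-bearing libraries (median 0.83) and with pancreatic CPM as a term (median 0.10, adjusted p = 0.924), 2 settings chosen after seeing the data. In this comparison edgeR's quasi-likelihood test called 177 genes higher and 41 lower after Benjamini-Hochberg adjustment. For male-biased genes, 2 of 14 measured genes fell (8 adjusted over the list alone), median log2 fold change -0.76, camera adjusted p = 3.04e-09, or 0.0974 with an estimated correlation. For female-biased genes, 1 of 12 measured genes rose (4 adjusted over the list alone), median log2 fold change 1.06, camera adjusted p = 5.46e-05, or 0.0974 with an estimated correlation. The Moxd1 call was lost with sequencing lane as a term, with only these groups in the fit, and without Control 28D replicate 10 or 11 or DDC+Cont replicate 25, 26 or 29 (adjusted p from 0.0582 to 0.163). The count of 218 called genes was 129 without Control 28D replicate 11, 133 without DDC+Cont replicate 25 and 133 without DDC+Cont replicate 26. The lower count of 41 came to 22 to 25 genes without any 1 of Control 28D replicates 9, 10, 11 and 13 and DDC+Cont replicates 25, 26 and 29.

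The interaction, the DDC effect at 28D minus that at 0D, tested how far the DDC change differed between the stages. Spp1 (log2 difference -3.75 ± 0.29), Col1a1 (-3.07 ± 0.73), Timp1 (-6.54 ± 0.99), Epcam (-2.60 ± 0.36), Krt8 (-2.74 ± 0.22) and Nqo1 (-2.32 ± 0.38) had smaller DDC effects at 28D. Lcn2, an iron-scavenging acute phase protein (-7.90 ± 1.40), Cxcl5 (-7.86 ± 1.49) and Gpx2 (-6.58 ± 1.62) had the largest negative differences among named genes. Lcn2 was 0.993 ± 0.326 CPM in Control 0D and 251 ± 77.1 CPM in DDC 0D, but 170 ± 184 CPM in Control 28D and 183 ± 150 CPM in DDC+Cont, so its difference reflects the higher level of the 28D controls. Pitx3 (10.23 ± 1.67), Hsd3b5 (9.65 ± 1.38) and Serpina4-ps1 (8.87 ± 1.98) had the largest positive ones. DDC 0D held no count of Pitx3, so its fitted value depends on the prior count and is no bound. For the extracellular matrix list, 26 genes had a smaller DDC effect at 28D (27 adjusted over the list alone), median log2 fold change -1.76, camera adjusted p = 3.37e-19, or 0.0450 with an estimated correlation. For bile duct genes 14 had a smaller effect (14 adjusted over the list alone), median log2 fold change -2.60, camera adjusted p = 2.32e-09, or 0.0450 with an estimated correlation, and for hepatocyte identity 13 had a difference above 0 (15 adjusted over the list alone), median log2 fold change 0.62, camera adjusted p = 1.37e-07, or 0.0450 with an estimated correlation. NRF2 targets had 15 smaller effects (16 adjusted over the list alone), median log2 fold change -1.64, camera adjusted p = 2.32e-09, or 0.0584 with an estimated correlation. The test called 2087 genes with a positive and 2520 with a negative difference. Across genes, which are not independent replicates, the DDC effects of the 2 stages had a Pearson r of 0.581 ± 0.0927 (jackknife SE over libraries) and a Spearman rho of 0.464. Without a low-count filter r was 0.368. Of the genes called at 0D, 74.4% had the same sign at 28D. Both stages called 172 genes higher, where 48.8 would coincide by chance, 25 lower (10.0 by chance) and 3 in opposite directions.

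HFD without DDC (HFD against Control 28D) raised a narrow set of drug-metabolism genes. Cyp2b10, the usual reporter of the xenobiotic receptor CAR, stood at 686 ± 136 CPM against 13.1 ± 8.02 CPM (n = 6 and 5), a log2 fold change of 5.71 ± 0.62. Cyp2b9 (5.53 ± 1.08) and Cyp2c55 (3.52 ± 0.44), further CAR-inducible P450 genes, rose, while Cyp2c40 (-4.50 ± 0.90), Tspyl4 (-1.55 ± 0.21) and Acmsd, a decarboxylase of tryptophan breakdown (-1.38 ± 0.24), fell. Of the CAR and PXR targets, 5 of 18 measured genes rose (10 adjusted over the list alone), median log2 fold change 0.50, camera adjusted p = 1.50e-20, or 0.00765 with an estimated correlation. Of the periportal genes, 2 of 15 measured genes fell (9 adjusted over the list alone), median log2 fold change -0.46, camera adjusted p = 7.56e-10, or 0.146 with an estimated correlation, both of the urea cycle: Cps1 (-0.59 ± 0.093) and Asl (-0.63 ± 0.13). Of the fatty acid synthesis genes, 0 of 20 measured genes fell (5 adjusted over the list alone), median log2 fold change -0.56, camera adjusted p = 2.08e-05, or 0.470 with an estimated correlation. edgeR's quasi-likelihood test called 31 genes higher and 23 lower, DESeq2 called 135 in all, and a fit of only these 2 groups called 105. The count of 54 genes was 34, 26, 25 and 26 without Control 28D replicates 9, 10, 11 and 13, and 35, 31 and 29 without HFD replicates 14, 16 and 17. The lower count of 23 was 41 without Control 28D replicate 12 and 14 without HFD replicate 19. HFD held 1 and Control 28D 0 libraries with over 1000 CPM of pancreatic enzymes. The pancreas and fat list was called (median log2 fold change 7.86, camera adjusted p = 0.00985, or 0.700 with an estimated correlation), a call lost without HFD replicate 14, which held 5569 CPM (median 3.83, adjusted p = 0.0654), and with pancreatic CPM as a term, a setting chosen after seeing the data (0.858). The Cyp2c40 call was lost without Control 28D replicate 10 (adjusted p = 0.0580), and that of Asl without Control 28D replicate 10 or 11 or HFD replicate 16 or 19 (adjusted p from 0.0534 to 0.0701).

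After DDC, HFD (DDC+HFD against DDC+Cont) again raised Cyp2b10 (log2 fold change 6.12 ± 0.64) and Cyp2c55 (3.15 ± 0.46), with the pseudogene Cyp2c53-ps at 3.39 ± 0.68. Neutrophil granule genes also rose, with myeloperoxidase, Mpo, at 3.77 ± 0.78 and neutrophil elastase, Elane, at 3.22 ± 0.59. Of the neutrophil list, 11 of 14 measured genes rose (13 adjusted over the list alone), median log2 fold change 2.53, camera adjusted p = 8.92e-09, or 0.370 with an estimated correlation. Of the CAR and PXR targets, 6 of 18 measured genes rose (8 adjusted over the list alone), median log2 fold change 0.42, camera adjusted p = 1.11e-10, or 0.186 with an estimated correlation. Of the acute phase list, 3 of 24 measured genes rose (8 adjusted over the list alone), median log2 fold change 0.94, camera adjusted p = 3.79e-08, or 0.618 with an estimated correlation. Etnppl, a phospholyase of phosphoethanolamine (-1.99 ± 0.38), Cyp4a12b (-1.95 ± 0.49) and the transcriptional regulator Id3 (-1.68 ± 0.23) fell. DDC+HFD held 3 libraries and DDC+Cont 1 with over 1000 CPM of pancreatic enzyme transcripts, and the clock score was 0.753 ± 1.31 (n = 6) against 2.44 ± 0.117 (n = 5, exact permutation test, p = 0.0195, adjusted p = 0.0571, which does not pass). With only these groups in the fit the calls of Mpo, Elane, Etnppl and Cyp4a12b were lost (adjusted p = 0.174, 0.137, 0.0555 and 0.202), and that of Cyp4a12b also without DDC+Cont replicate 25 or 28 or DDC+HFD replicate 33 or 37 (adjusted p from 0.0512 to 0.0635) and with the clock score as a term, a setting chosen after seeing the data (0.0561). There were 268 genes called higher and 220 lower, and 101 genes in a fit of only these groups and 299 with sequencing lane as a term. Their total of 488 was 301 without DDC+Cont replicate 24, 167 without replicate 25, 288 without replicate 28 and 225 without DDC+HFD replicate 33. Without DDC+HFD replicate 30 the total was 715 and the higher count 419.

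Ethanol added to HFD without DDC (EtOH against HFD) raised genes of oxidant defence and drug metabolism. Nqo1 stood at 51.0 ± 11.6 CPM against 9.38 ± 2.22 CPM (n = 4 and 6), a log2 fold change of 2.44 ± 0.25. The largest increases were in Cyp2a4, a steroid hydroxylase (7.70 ± 0.80), the carbonyl reductase Cbr3 (7.26 ± 0.53), Slc7a11 (6.24 ± 0.86), Cyp2b13 (6.23 ± 0.56) and the glutathione transferase Gsta1 (6.13 ± 0.49). Cyp2a4 ran at 266 ± 287 CPM against 1.34 ± 0.637 CPM. Of the NRF2 targets, 18 of 23 measured genes rose (19 adjusted over the list alone), median log2 fold change 1.72, camera adjusted p = 9.24e-44, or 6.21e-05 with an estimated correlation. They included the efflux pump Abcc4 (4.88 ± 0.32) and the epoxide hydrolase Ephx1 (1.86 ± 0.16). Of the CAR and PXR targets, 10 of 18 measured genes rose (15 adjusted over the list alone), median log2 fold change 0.73, camera adjusted p = 7.35e-09, or 0.148 with an estimated correlation. Cyp2a5 stood at 3.58 ± 0.29, while Cyp2b10 stood at 1.20 ± 0.51 (adjusted p = 0.119). Reads of the near-identical Cyp2a and Cyp2b copies can be lost or shared among members, so the values of single members are uncertain. For female-biased genes, 6 of 12 measured genes rose (6 adjusted over the list alone), median log2 fold change 1.28, camera adjusted p = 2.50e-04, or 0.263 with an estimated correlation. Among them was Cyp2b9 (4.37 ± 0.74).

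Sterol and lipid synthesis genes fell with ethanol. Of the cholesterol synthesis list, 13 of 24 measured genes fell (20 adjusted over the list alone), median log2 fold change -0.79, camera adjusted p = 1.26e-11, or 0.265 with an estimated correlation. They included the squalene epoxidase Sqle (-1.36 ± 0.26) and the phosphomevalonate kinase Pmvk (-1.29 ± 0.21). Of the fatty acid synthesis list, 7 of 20 measured genes fell (8 adjusted over the list alone), median log2 fold change -0.76, camera adjusted p = 9.86e-05, or 0.531 with an estimated correlation. The elongase Elovl5 stood at -1.35 ± 0.21. Among lipid droplet genes, 5 of 17 measured genes rose (5 adjusted over the list alone), median log2 fold change 0.32, camera adjusted p = 7.21e-04, or 0.265 with an estimated correlation. The droplet-fusing protein Cidec stood at 1.84 ± 0.36. The fatty acid importer Cd36 was also higher (1.19 ± 0.15). Of the male-biased genes, 8 of 14 measured genes fell (10 adjusted over the list alone), median log2 fold change -1.27, camera adjusted p = 6.60e-06, or 0.265 with an estimated correlation. Hsd3b5 stood at -7.67 ± 0.97 and Slco1a1 at -3.99 ± 0.57. Other large decreases were in the trefoil peptide Tff3 (-6.60 ± 1.02), Serpina4-ps1 (-5.29 ± 1.40), the adhesion receptor Adgrf1 (-5.18 ± 0.57) and Slc4a1, the anion exchanger of red cells (-4.93 ± 1.18). Of the extracellular matrix list, 7 of 28 measured genes rose (8 adjusted over the list alone), median log2 fold change 0.42, camera adjusted p = 7.27e-04, or 0.650 with an estimated correlation. Col4a1 stood at 0.62 ± 0.12 and the lysyl oxidase Loxl2 at 1.21 ± 0.19, while Col1a1 stood at 0.44 ± 0.48 (adjusted p = 0.609). Cyp2e1 stood at -0.50 ± 0.22 (adjusted p = 0.133), the alcohol dehydrogenase Adh1 at 0.25 ± 0.13 (adjusted p = 0.208) and the aldehyde dehydrogenase Aldh2 at 0.13 ± 0.11 (adjusted p = 0.480).

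Clock genes moved in the same libraries: the clock output gene Dbp (3.54 ± 0.77) was higher and the repressor Cry1 (-1.32 ± 0.25) lower. The clock score was -0.404 ± 1.19 (n = 4) in EtOH against 1.78 ± 0.686 (n = 6) in HFD (exact permutation test, p = 0.00476, the smallest it can give, adjusted p = 0.0286 over 6 comparisons). Without EtOH replicate 21, at -2.19, the EtOH mean was 0.190 ± 0.0474 (n = 3, exact permutation test, p = 0.0238). Of the red blood cell list, 3 of 4 measured genes fell (4 adjusted over the list alone), median log2 fold change -2.81, camera adjusted p = 0.0357, or 0.451 with an estimated correlation, and of the interferon response, 5 of 26 measured genes fell (5 adjusted over the list alone), median log2 fold change -0.30, camera adjusted p = 0.00697, or 0.734 with an estimated correlation. edgeR's quasi-likelihood test called 1126 genes higher and 806 lower with EtOH. HFD replicate 14 held 5569 CPM of pancreatic enzyme transcripts, and without it the calls of Slc4a1 (log2 fold change -1.57, adjusted p = 0.0948) and of the red blood cell list (adjusted p = 0.141) were lost. The red blood cell call was also lost under the stricter low-count filter and with sequencing lane as a term (adjusted p = 0.0920 and 0.0640), and without the pancreas-bearing libraries and with pancreatic CPM as a term, 2 settings chosen after seeing the data (0.105 and 0.0613). It was lost too without HFD replicate 18 or EtOH replicate 20 or 22 (adjusted p = 0.0768, 0.0563 and 0.0904), and the interferon response call without EtOH replicate 22 (adjusted p = 0.0533).

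Ethanol after DDC (DDC+EtOH against DDC+HFD) raised NRF2 targets. Nqo1 stood at 47.9 ± 23.7 CPM against 9.50 ± 2.48 CPM (n = 6 and 6), a log2 fold change of 2.33 ± 0.23. The largest increases were in Cyp2a4 (7.20 ± 0.74), Slc7a11 (6.86 ± 0.83), Cyp2b13 (6.39 ± 0.53), Cbr3 (5.86 ± 0.50) and Gsta1 (5.80 ± 0.48). Of the NRF2 targets, 18 of 23 measured genes rose (21 adjusted over the list alone), median log2 fold change 1.93, camera adjusted p = 6.47e-50, or 1.61e-05 with an estimated correlation. Abcc4 stood at 4.23 ± 0.30 and Ephx1 at 2.00 ± 0.15. Of the CAR and PXR targets, 12 of 18 measured genes rose (14 adjusted over the list alone), median log2 fold change 0.86, camera adjusted p = 3.69e-12, or 0.0676 with an estimated correlation. Cyp2a5 stood at 3.78 ± 0.28. Of the cholesterol synthesis genes, 15 of 24 measured genes fell (18 adjusted over the list alone), median log2 fold change -0.67, camera adjusted p = 2.37e-10, or 0.342 with an estimated correlation. They included Pmvk (-1.31 ± 0.18). Of the extracellular matrix list, 13 of 28 measured genes rose and 1 fell (18 and 2 adjusted over the list alone), median log2 fold change 0.54, camera adjusted p = 1.07e-06, or 0.383 with an estimated correlation. Col4a1 (0.63 ± 0.10), Loxl2 (1.33 ± 0.17) and Sparc, a collagen-binding matricellular protein (0.73 ± 0.13), rose, and fibronectin, Fn1, fell (-0.54 ± 0.17), a call lost with only these groups in the fit and without DDC+HFD replicate 30 or 33 or DDC+EtOH replicate 39, 40 or 43 (adjusted p from 0.0529 to 0.0874). Col1a1 stood at 15.8 ± 9.95 CPM against 7.51 ± 2.80 CPM (log2 fold change 1.08 ± 0.40, adjusted p = 0.0580). Of the fatty acid oxidation genes, 8 of 23 measured genes rose and 2 fell (9 and 2 adjusted over the list alone), median log2 fold change 0.19, camera adjusted p = 2.49e-04, or 0.417 with an estimated correlation. Cyp4a14, an omega-hydroxylase induced by PPAR-alpha, stood at 3.53 ± 0.77 and the acyl-CoA thioesterase Acot2 at 2.94 ± 0.44.

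Neutrophil granule genes were lower with ethanol after DDC. S100a8 ran at 5.57 ± 4.06 CPM against 101 ± 102 CPM. The log2 fold change of Ngp was -6.11 ± 0.95, with the antimicrobial peptide Camp at -6.03 ± 0.93, Mpo at -5.35 ± 0.82, Elane at -5.45 ± 0.67 and proteinase 3, Prtn3, at -4.01 ± 0.55. Of the neutrophil list, 11 of 14 measured genes fell (12 adjusted over the list alone), median log2 fold change -3.52, camera adjusted p = 8.35e-08, or 0.342 with an estimated correlation. The red cell score (red blood cell list) was also lower, at 0.513 ± 0.546 against 1.39 ± 0.734 (exact permutation test, p = 0.0346). The neutrophil score less the red cell score had a p of 0.0758, so blood content is not separated out. The red cell p was from 0.0541 to 0.0801 without DDC+HFD replicate 32, 33 or 35 or DDC+EtOH replicate 39, 40 or 43, and that of the score difference was 0.0152 without DDC+HFD replicate 30. Of the acute phase list, 8 of 24 measured genes fell (9 adjusted over the list alone), median log2 fold change -0.77, camera adjusted p = 5.72e-05, or 0.524 with an estimated correlation. They included the fibrinogen chains Fga (-0.98 ± 0.22) and Fgb (-0.97 ± 0.21). Of the male-biased genes, 1 of 14 measured genes rose and 8 fell (1 and 10 adjusted over the list alone), median log2 fold change -1.71, camera adjusted p = 8.35e-08, or 0.300 with an estimated correlation. Hsd3b5 stood at -6.83 ± 0.89 and Elovl3 at -4.45 ± 0.63. The riser among the male-biased genes was the glutathione transferase Gstp1 (1.05 ± 0.17). Female-biased genes went the other way: 4 of 12 measured genes rose (5 adjusted over the list alone), median log2 fold change 1.18, camera adjusted p = 3.69e-05, or 0.162 with an estimated correlation. Of the bile acid synthesis genes, 1 of 14 measured genes rose and 7 fell (1 and 8 adjusted over the list alone), median log2 fold change -0.33, camera adjusted p = 0.00625, or 0.383 with an estimated correlation. The sterol 27-hydroxylase Cyp27a1 stood at -0.82 ± 0.12 and the oxysterol hydroxylase Cyp39a1 at 1.17 ± 0.18. Tff3 (-5.11 ± 0.66), Adgrf1 (-3.51 ± 0.40) and the anion carrier Slc22a28 (-3.29 ± 0.41) were among the largest decreases. For p53 targets, 6 of 18 measured genes rose (7 adjusted over the list alone), median log2 fold change 0.27, camera adjusted p = 0.0309, or 0.397 with an estimated correlation. In the clock score the groups stood at -0.615 ± 1.81 and 0.753 ± 1.31 (exact permutation test, p = 0.162, adjusted p = 0.200). DDC+HFD held 3 and DDC+EtOH 2 libraries with over 1000 CPM of pancreatic enzymes. edgeR's quasi-likelihood test called 1224 genes higher and 1151 lower, 804 in all with only these groups in the fit and 1275 without the pancreas-bearing libraries, a setting chosen after seeing the data. The bile acid synthesis call was lost without those libraries (adjusted p = 0.0923), and that of the p53 targets without DDC+HFD replicate 36 or DDC+EtOH replicate 39 or 40 (adjusted p = 0.0509, 0.0749 and 0.138) and with pancreatic CPM as a term (0.0803).

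**Figure D2:**
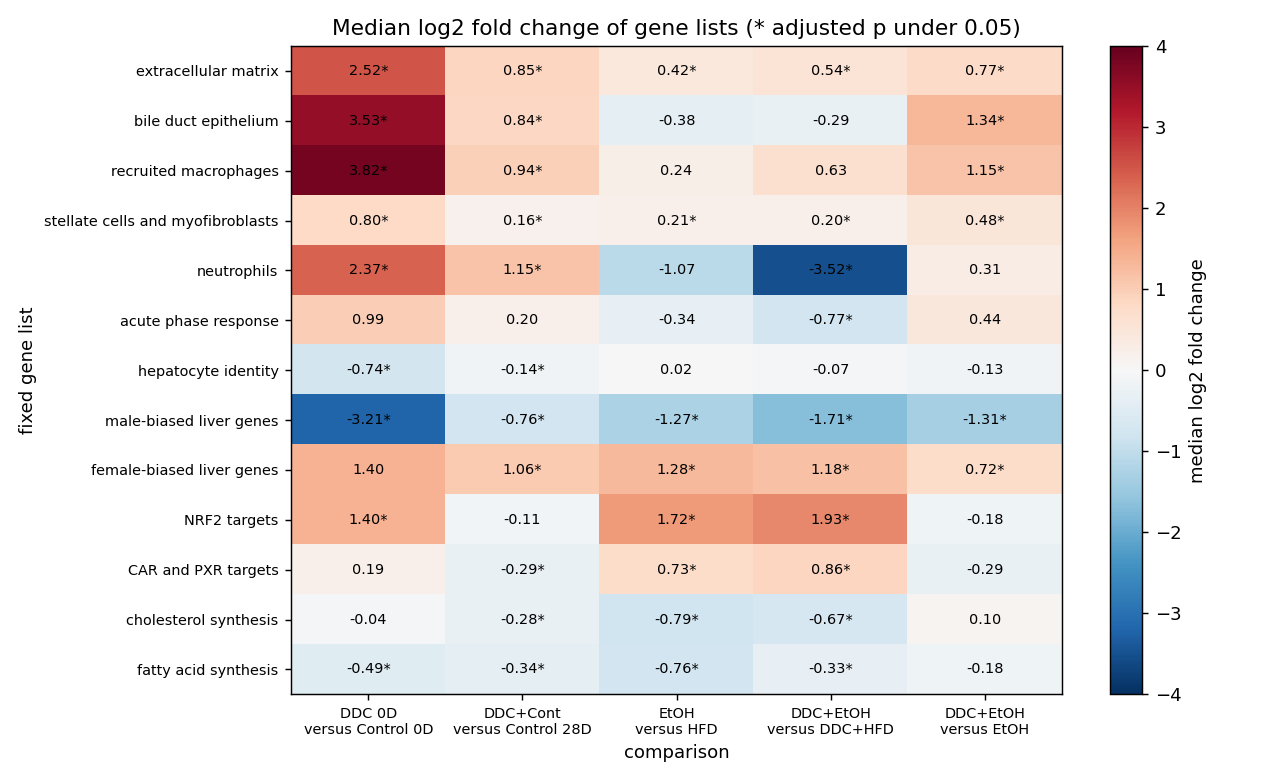
Median log2 fold change of 13 fixed gene lists in the 5 main comparisons, with an asterisk where camera's adjusted p was under 0.05 at an inter-gene correlation of 0.01. The NRF2 target list stood at 1.72 in EtOH against HFD and 1.93 in DDC+EtOH against DDC+HFD.

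Whether ethanol acted differently after DDC was tested by the interaction of the 4 groups given HFD. No gene passed: edgeR's quasi-likelihood test called 0 genes, 739 had an unadjusted p under 0.05 and the lowest adjusted p was 0.448. DESeq2 called 4: Acer2 (-0.66 ± 0.15), Ctsa (-0.36 ± 0.078), Mb (-32.6 ± 5.07) and Reg2 (22.4 ± 4.02), the last 2 too extreme to read as folds. These 4, outside the naming rule, were named after their values were seen, and Mb was under edgeR's low-count filter. NRF2 targets had a median log2 difference of -0.03 (0 called, 0 adjusted over the list alone, camera adjusted p = 0.749). As a list, neutrophil genes differed (0 of 14 genes called, 7 lower adjusted over the list alone, median log2 fold change -2.84, camera adjusted p = 9.01e-11, or 0.464 with an estimated correlation), and so did acute phase genes (0 of 24 called, 3 lower adjusted over the list alone, median log2 fold change -0.52, camera adjusted p = 1.21e-05, or 0.864 with an estimated correlation). Elane had a log2 difference of -4.27 ± 1.28 (adjusted p = 0.533). Across genes, which are not independent replicates, the ethanol effects of the 2 arms had a Pearson r of 0.638 ± 0.143 (jackknife SE over libraries) and a Spearman rho of 0.657, and r was 0.315 without a low-count filter and 0.347 by DESeq2. Both arms called 692 genes higher, where 96.0 would coincide by chance, 452 lower (64.6 by chance) and 0 in opposite directions, and 1871 of the 1932 genes called without DDC had the same sign after it (96.8%). The slope over those genes was 0.748. In the self-test, which had no other group differences, this interaction recovered 50.7% of genes given a 2-fold difference. Smaller ones were mostly not detectable there.

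**Figure D3:**
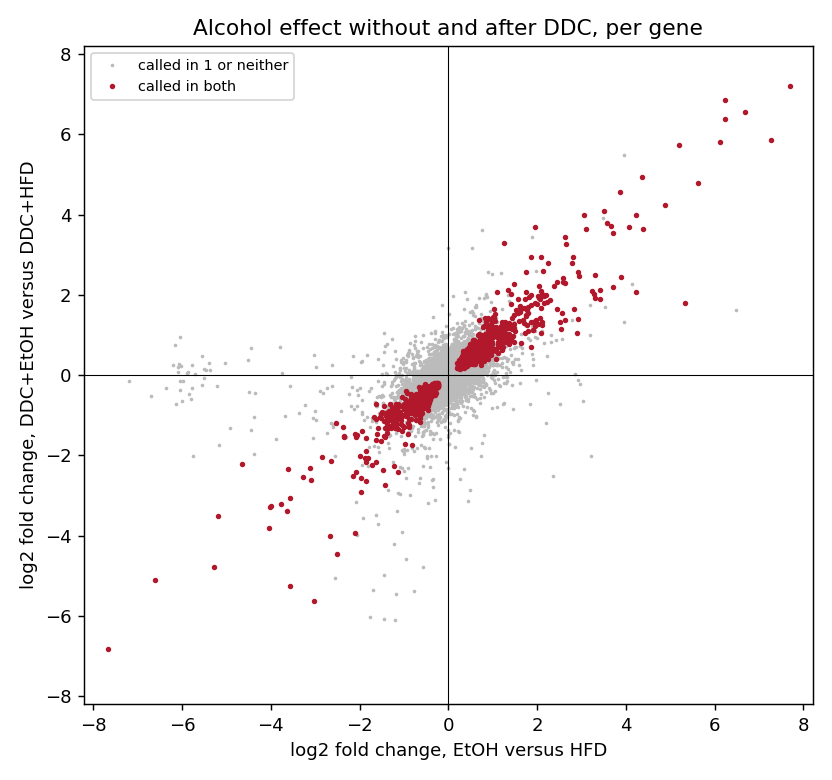
Log2 fold change of each tested gene in EtOH against HFD (x axis) and in DDC+EtOH against DDC+HFD (y axis), with genes called in both in red. Of the red genes, 692 were higher and 452 lower in both arms.

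Earlier DDC in animals that all received ethanol (DDC+EtOH against EtOH) left more ductular and stellate transcripts. Spp1 stood at 124 ± 41.5 CPM against 49.2 ± 4.86 CPM (n = 6 and 4), a log2 fold change of 1.33 ± 0.20. Lrtm2 (4.65 ± 0.57), Ntrk2 (4.41 ± 0.52), the matrix adhesion protein Svep1 (2.07 ± 0.31), the collagen receptor kinase Ddr1 (2.01 ± 0.31) and the podosome adaptor Sh3pxd2b (1.98 ± 0.32) rose most. Elovl3 (-3.40 ± 0.63), the male-specific Cyp4a12a (-2.34 ± 0.63), Susd4 (-2.27 ± 0.32), the T cell gene Themis (-2.02 ± 0.49) and the droplet coat protein Plin4 (-1.73 ± 0.42) fell most. Of the bile duct list, 12 of 19 measured genes rose (14 adjusted over the list alone), median log2 fold change 1.34, camera adjusted p = 6.05e-17, or 0.00444 with an estimated correlation. Epcam stood at 2.33 ± 0.27 and Tspan8 at 2.20 ± 0.32. Of the extracellular matrix list, 13 of 28 measured genes rose (18 adjusted over the list alone), median log2 fold change 0.77, camera adjusted p = 8.33e-16, or 0.0706 with an estimated correlation. Lum stood at 1.89 ± 0.22 and Col1a1 at 1.41 ± 0.46 (adjusted p = 0.0600). Of the stellate list, 4 of 15 measured genes rose (8 adjusted over the list alone), median log2 fold change 0.48, camera adjusted p = 5.03e-06, or 0.0335 with an estimated correlation. Pdgfra stood at 1.37 ± 0.16. Of the recruited macrophages, 9 of 16 measured genes rose (12 adjusted over the list alone), median log2 fold change 1.15, camera adjusted p = 7.55e-11, or 0.0706 with an estimated correlation. Cx3cr1 stood at 1.93 ± 0.24. For male-biased genes, 6 of 14 measured genes fell (9 adjusted over the list alone), median log2 fold change -1.31, camera adjusted p = 5.99e-12, or 0.0706 with an estimated correlation. DDC+EtOH held 2 and EtOH 0 libraries with over 1000 CPM of pancreatic enzymes.

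Lipid genes were lower in the same contrast: of the fatty acid oxidation list, 4 of 23 measured genes fell (9 adjusted over the list alone), median log2 fold change -0.29, camera adjusted p = 1.98e-04, or 0.429 with an estimated correlation, and of the lipid droplet list, 4 of 17 measured genes fell (4 adjusted over the list alone), median log2 fold change -0.16, camera adjusted p = 0.00459, or 0.338 with an estimated correlation. edgeR's quasi-likelihood test called 591 genes higher and 369 lower, 243 in all with only these groups in the fit and 1468 without the pancreas-bearing libraries, a setting chosen after seeing the data. The total of 960 was 573, 560 and 545 without EtOH replicates 21, 22 and 23, 1477 without DDC+EtOH replicate 38 and 631 without replicate 39. The lower count of 369 was 224 without EtOH replicate 20 and 225 without DDC+EtOH replicate 40. With only these groups in the fit the calls of Elovl3, Cyp4a12a and Themis were lost (adjusted p = 0.0605, 0.144 and 0.0764), and without EtOH replicate 23 those of Cyp4a12a and Themis (0.0541 and 0.0689).

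With HFD alone as the second treatment (DDC+HFD against HFD), earlier DDC raised Lrtm2 (log2 fold change 5.53 ± 0.59), Gpnmb (3.95 ± 0.65) and the metallothionein Mt2 (3.85 ± 0.80), and lowered Trhde (-2.65 ± 0.37), Hsd3b5 (-2.41 ± 0.58) and Slco1a1 (-2.00 ± 0.44). Of the bile duct list, 11 of 19 measured genes rose (16 adjusted over the list alone), median log2 fold change 1.32, camera adjusted p = 2.66e-17, or 0.00379 with an estimated correlation. Epcam stood at 1.87 ± 0.22, Spp1 at 1.33 ± 0.17 and Krt19 at 1.79 ± 0.32. Of the stellate list, 7 of 15 measured genes rose (8 adjusted over the list alone), median log2 fold change 0.36, camera adjusted p = 2.74e-08, or 0.00493 with an estimated correlation. Of the extracellular matrix list, 15 of 28 measured genes rose and 1 fell (20 and 1 adjusted over the list alone), median log2 fold change 0.66, camera adjusted p = 1.20e-11, or 0.168 with an estimated correlation. Of the neutrophil list, 11 of 14 measured genes rose (13 adjusted over the list alone), median log2 fold change 3.40, camera adjusted p = 1.98e-07, or 0.250 with an estimated correlation. Ngp stood at 4.82 ± 0.87 and Mpo at 4.26 ± 0.76. DDC+HFD held 3 and HFD 1 libraries with over 1000 CPM of pancreatic enzymes. The test called 1143 genes higher and 788 lower, 1213 in all without HFD replicate 15, and with only these groups in the fit Hsd3b5 and Slco1a1 lost their calls (adjusted p = 0.101 and 0.0540). The lower count was 436 without HFD replicate 15, 486 without HFD replicate 17 and 496 without DDC+HFD replicate 33.

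DDC+EtOH against Control 28D joined DDC, HFD and ethanol, since Control 28D received BD at both stages, so the changes below cannot be assigned to a single treatment. Cyp2b13 (10.42 ± 0.83), Cyp2b9 (10.38 ± 1.13) and Cyp2a4 (9.53 ± 0.93) rose most, and Moxd1 (-10.01 ± 1.23), Hsd3b5 (-9.80 ± 0.92) and Pitx3 (-7.12 ± 0.84) fell most. Col1a1 was 15.8 ± 9.95 CPM against 2.65 ± 0.991 CPM (n = 6 and 5), a log2 fold change of 2.57 ± 0.47. Of the extracellular matrix list, 25 of 28 measured genes rose (25 adjusted over the list alone), median log2 fold change 1.38, camera adjusted p = 2.59e-18, or 0.0382 with an estimated correlation. Of the NRF2 targets, 18 of 23 measured genes rose and 1 fell (19 and 1 adjusted over the list alone), median log2 fold change 1.39, camera adjusted p = 9.69e-19, or 0.0132 with an estimated correlation. Of the CAR and PXR targets, 15 of 18 measured genes rose (16 adjusted over the list alone), median log2 fold change 1.58, camera adjusted p = 2.32e-11, or 0.0360 with an estimated correlation. For male-biased genes, 12 of 14 measured genes fell (13 adjusted over the list alone), median log2 fold change -3.42, camera adjusted p = 2.85e-19, or 0.0132 with an estimated correlation. For female-biased genes, 10 of 12 measured genes rose (10 adjusted over the list alone), median log2 fold change 2.97, camera adjusted p = 3.34e-08, or 0.0279 with an estimated correlation. Of the fatty acid synthesis list, 17 of 20 measured genes fell (17 adjusted over the list alone), median log2 fold change -1.50, camera adjusted p = 5.00e-10, or 0.129 with an estimated correlation. Scd1 stood at -2.81 ± 0.37 and the fatty acid synthase Fasn at -1.82 ± 0.48. edgeR's quasi-likelihood test called 2597 genes higher and 2267 lower. Over 1000 CPM of pancreatic enzymes was held by 2 DDC+EtOH and 0 Control 28D libraries.

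The control groups of the 2 stages (Control 28D against Control 0D) gave the background of the second treatment period. Lcn2 (7.45 ± 1.20), Moxd1 (7.15 ± 1.18) and the serum amyloid Saa2 (7.05 ± 1.64) rose most, and G6pc2, a glucose-6-phosphatase subunit (-1.98 ± 0.46), Csad, an enzyme of taurine synthesis (-1.92 ± 0.30), and Cyp3a11 (-1.91 ± 0.31) fell most. Of the acute phase list, 13 of 24 measured genes rose (22 adjusted over the list alone), median log2 fold change 1.44, camera adjusted p = 5.56e-27, or 0.115 with an estimated correlation. They included orosomucoid Orm2 (5.29 ± 1.08) and haptoglobin, Hp (1.90 ± 0.37). Of the cytokine list, 6 of 21 measured genes rose (11 adjusted over the list alone), median log2 fold change 1.02, camera adjusted p = 4.85e-12, or 0.115 with an estimated correlation. The chemokine Cxcl1 stood at 4.61 ± 0.68. Of the neutrophil list, 3 of 14 measured genes rose (10 adjusted over the list alone), median log2 fold change 2.99, camera adjusted p = 1.18e-12, or 0.157 with an estimated correlation. The labels do not say whether Control 28D animals carried the gastric tube. The test called 233 genes higher and 120 lower, 353 in all, and 688 in all with only these groups in the fit, 592 by DESeq2, 535 without the pancreas-bearing libraries and 533 with pancreatic CPM as a term, the last 2 settings being chosen after seeing the data. The total was 137, 164 and 119 without Control 0D replicates 2, 3 and 4 and 209 without Control 28D replicate 13, and the lower count was 78, 68 and 78 without Control 28D replicates 9, 10 and 11. The G6pc2 call was lost without Control 0D replicate 2 or 4 (adjusted p = 0.0719 and 0.0614) and the Saa2 call without replicate 2, 3 or 4 (0.0666, 0.0599 and 0.0694).

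**Figure D4:**
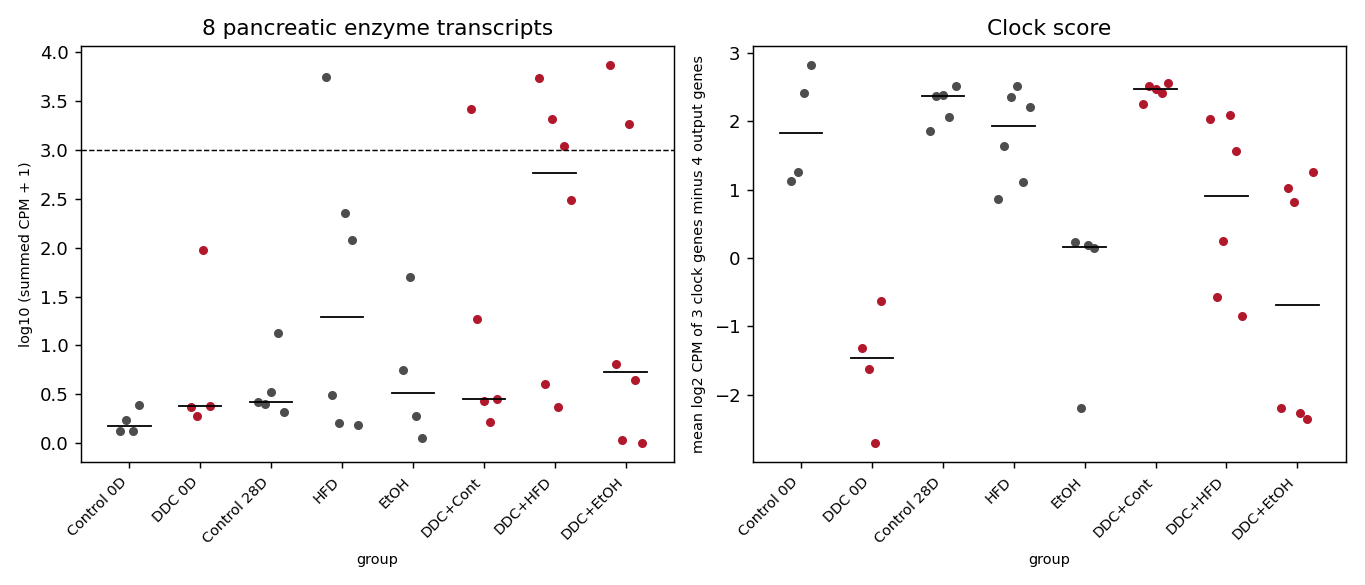
Left, log10 of the summed CPM of 8 pancreatic enzyme transcripts plus 1 in each of the 40 libraries by group, with a dashed line at 1000 CPM. Right, the clock score in log2 units, with horizontal bars at group medians; 7 libraries lay above the line, from 1082 to 7336 CPM.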

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

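The tests of pancreatic carry-over, of earlier DDC and of blood content were chosen only after their results were seen. The tests of time of day and of pancreatic libraries for NRF2 targets rest on fits chosen after seeing the data, and leaving out single libraries was planned. A sample was singled out when its gap to the nearest library of its group was large for the group's range (Dixon's test at 95%), and chance does that in about 1 in 20 groups. This happened in 9 of 72 groups of quality measures, 21 of 280 groups of list scores (mean log2 CPM) and 9 of 100 groups of named genes (log2 CPM).

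Summed CPM of 8 pancreatic enzymes stood apart at 5569 in HFD replicate 14, 2612 in DDC+Cont replicate 24 and 7336 in DDC+EtOH replicate 38, and at low levels of 94.2 in DDC 0D replicate 7, 12.3 in Control 28D replicate 12 and 49.2 in EtOH replicate 21. Pancreatic tissue carried into 7 liver samples may account for the values over 1000 CPM: 14 other acinar genes kept a nearly fixed ratio to the enzymes over those libraries (median SD of the log2 ratio 0.184, while the enzyme sum itself varied with an SD of 1.02). Of the libraries from animals given DDC before a second treatment, 6 of 17 were over 1000 CPM, against 1 of 15 without DDC (Fisher's exact test, two-sided, p = 0.0881). That p does not show that the shares were equal, so an effect of earlier DDC and a difference in dissection cannot be told apart with these numbers.

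NRF2 targets were higher with ethanol in both arms. Sampling at another time of day, as the whole cause, was argued against: with the clock score as a term, the list's median kept 90.2% of its size without DDC and 103% after DDC. Without the libraries holding pancreatic transcripts it kept 104% without DDC and 77.8% after DDC, where the list was still called (camera adjusted p = 9.26e-41), so a part of the size in the DDC arm stays open. Ethanol, which the design sets between the groups, stays among the open explanations.

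Neutrophil genes were lower in DDC+EtOH than in part of DDC+HFD, as given above. Camera's adjusted p with any 1 library left out, at most 7.84e-06, does not measure spread between animals. The neutrophil score's exact permutation p reached 0.0476, so a single library was only weakly argued against. Less blood in the DDC+EtOH samples may account for part of the gap: the red cell score was also lower (exact p = 0.0346), beside a neutrophil score of 0.569 ± 0.660 against 3.04 ± 2.01 (exact p = 0.0281). The neutrophil score less the red cell score was 0.0562 ± 0.859 against 1.65 ± 1.79 (exact p = 0.0758), so they are not separated. That p and the red cell one crossed 0.05 without single libraries. Ethanol and a rise in part of DDC+HFD stay open.

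Other libraries stood apart from their group as follows. Control 0D replicate 2 had 6.58% of reads not aligned, replicate 4 a bile duct score of 1.25 and replicate 1 a Cxcl5 level of -2.21. DDC 0D replicate 7 had a pancreas and fat score of 2.46 and replicate 8 a stellate score of 4.98. Control 28D replicate 12 had a fatty acid synthesis score of 7.69 and replicate 11 an alcohol metabolism score of 8.59. HFD replicate 14 had scores of 3.09 for B and plasma cells, 4.84 for red blood cells and 2.61 for the cell cycle, with Cbr3 at 0.68 and Slc4a1 at 5.83, and HFD replicate 19 had a bile transport score of 6.75. EtOH replicate 20 had 22.5% of reads on no feature. EtOH replicate 21 had a clock score of -2.19 and a stellate score of 4.16, and replicate 23 a T and NK cell score of -0.86 with Cyp2b13 at 4.22.

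DDC+Cont replicate 26 had scores of 8.58 for periportal genes, 1.97 for the cell cycle and 2.95 for fetal liver genes, with Ntrk2 at 5.13 and Susd4 at 2.31, and DDC+Cont replicate 28 had Moxd1 at -1.50. DDC+HFD replicate 32 had scores of 6.99 for CAR and PXR targets, 7.98 for bile acid synthesis, 8.65 for fatty acid synthesis and 2.93 for female-biased genes, with Cyp2a4 at 3.93. DDC+EtOH replicate 43 had a Kupffer score of 6.04, replicate 41 a sinusoidal score of 5.62 with Tff3 at -2.88, and replicate 39 a fetal liver score of 3.00. The Tff3 level is that of no count.

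The DDC effect differed between 0D and 28D by its own test: the interaction called 4607 genes and 20 lists, of which 4 were called with an estimated correlation. Its log2 differences included Cxcl5 at -7.86, Gpx2 at -6.58 and Lcn2 at -7.90 (which rose by 7.45 between the stages' controls). They also included Hsd3b5 at 9.65, Serpina4-ps1 at 8.87 and Pitx3 at 10.23, which depends on the prior count. The alcohol interaction called 4 lists by camera, and 0 with an estimated correlation. Neutrophils and acute phase response were lower after DDC, as given above. For p53 targets the median log2 fold change was 0.28 (camera adjusted p = 0.00249, or 0.464 with an estimated correlation). For cell cycle it was 0.26 (0.0404, or 0.864). The cell cycle call was lost without HFD replicate 14, EtOH replicate 20, 21 or 22, DDC+HFD replicate 30, 36 or 37, or DDC+EtOH replicate 38, 40 or 41 (adjusted p from 0.0591 to 0.990). It was also lost with no low-count filter (adjusted p = 0.0782) and with pancreatic CPM as a term (0.0934), and without the pancreas-bearing libraries, a setting chosen after seeing the data, the list was called in the opposite direction (median -0.51, adjusted p = 0.00520).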

How the results depend on the processing

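The fits without the pancreas-bearing libraries, with pancreatic CPM as a term and with the clock score as a term were chosen after seeing the data. No paired analysis was possible because no replicate number is shared between groups. HFD against Control 28D called 54 genes, 105 with only the groups compared and 135 by DESeq2. DDC+HFD against DDC+Cont called 488, 299 with lane as a term and 101 with only the groups compared. DDC+EtOH against DDC+HFD called 2375, 804 with only the groups compared and 1275 without the pancreas-bearing libraries. DDC+EtOH against EtOH called 960, 243 and 1468 under the same settings. The alcohol interaction called 0 genes by edgeR, with 739 at an unadjusted p under 0.05, and 4 by DESeq2. Control 28D against Control 0D called 353, 688 with only the groups compared, 592 by DESeq2, 535 without the pancreas-bearing libraries and 533 with pancreatic CPM as a term. The correlation across genes of the 2 ethanol effects (0.638) was 0.315 with no filter, 0.347 by DESeq2 and 0.816 with the clock score. That of the 2 DDC effects (0.581) was 0.368, 0.473 and 0.454. The cause was not tested, except that a fit of only the groups compared, or without libraries, rests on fewer samples. With 1 library left out, calls ranged from 6851 to 7287 for DDC 0D against Control 0D, 129 to 247 for DDC+Cont against Control 28D, 4068 to 4678 for the DDC interaction and 25 to 73 for HFD against Control 28D. They ranged from 1368 to 1887 for EtOH against HFD, 167 to 715 for DDC+HFD against DDC+Cont, 1970 to 2550 for DDC+EtOH against DDC+HFD, 0 to 0 for the alcohol interaction by edgeR, 545 to 1477 for DDC+EtOH against EtOH and 1213 to 2174 for DDC+HFD against HFD. They ranged from 4069 to 4874 for DDC+EtOH against Control 28D and 119 to 339 for Control 28D against Control 0D. The correlations ranged from 0.559 to 0.707 (ethanol) and 0.512 to 0.592 (DDC). In these cases the direction of camera's test turned for a list called as reported, under the alternative, or in both. Called as reported only were pancreas and fat, whose median went with pancreatic CPM as a term from 6.89 to 0.10 (DDC+Cont against Control 28D) and from 7.86 to 0.13 (HFD against Control 28D), and cell cycle in DDC+EtOH against DDC+HFD, from 0.43 to 0.033 without the pancreas-bearing libraries. Those medians stayed above 0. The next lists were called under the alternative only. With the clock score, cholesterol synthesis stood at 0.40 (DDC interaction, -0.17 as reported) and -0.13 (DDC+HFD against DDC+Cont, 0.17 as reported). Without the pancreas-bearing libraries, B and plasma cells stood at -0.35 (HFD against Control 28D, 0.50 as reported, and -0.35 without HFD replicate 14) and 0.85 (DDC+HFD against HFD, -0.39 as reported), and cell cycle at -0.20 (HFD against Control 28D, 0.15 as reported). In the alcohol interaction without those libraries, cholesterol synthesis stood at -0.33 (0.061 as reported) and male-biased genes at 0.52 (-0.060 as reported). Cell cycle in the alcohol interaction was called in both, at 0.26 as reported and at -0.51 without those libraries. Among called genes that changed sign was gene Slc4a1, DDC+HFD versus HFD, without the pancreas-bearing libraries (0.51) and without HFD replicate 14 (0.77, in a range of -3.22 to 0.77 with 1 library left out). In DDC+EtOH against Control 28D, the pancreatic genes Cpa1, Cpb1, Ctrb1 and Pnlip stood at -0.81, -0.55, -0.27 and -0.30 without the pancreas-bearing libraries and at -0.97, -0.56, -0.090 and -0.42 with the clock score, and Cpa1 and Cpb1 at -0.55 and -0.30 with pancreatic CPM as a term. Uncalled sign changes were 576 of all 46809 gene values and 282 of all 8809 list values. Depth, 7197940 to 26398100 reads on genes, and 4 to 6 animals per group limit what folds under 2 can be seen.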

Other observations

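The fits with the clock score or without pancreas-bearing libraries were chosen after seeing the data, and the counts over other splits were planned. Further lists were called in DDC 0D against Control 0D. For Kupffer cell genes, 10 of 16 measured genes rose (10 adjusted over the list alone), median log2 fold change 1.20, camera adjusted p = 0.00222, or 0.431 with an estimated correlation. For stellate cell genes, 10 of 15 measured genes rose and 1 fell (10 and 1 adjusted over the list alone), median log2 fold change 0.80, camera adjusted p = 1.67e-04, or 0.0583 with an estimated correlation, with the globin Cygb at 2.27 ± 0.16. For fetal liver genes, 9 of 11 measured genes rose (9 adjusted over the list alone), median log2 fold change 1.71, camera adjusted p = 0.00195, or 0.0792 with an estimated correlation. Of the p53 targets, 13 of 18 measured genes rose and 1 fell (13 and 1 adjusted over the list alone), median log2 fold change 0.79, camera adjusted p = 0.00232, or 0.136 with an estimated correlation. Of the neutrophil genes, 6 of 14 measured genes rose (6 adjusted over the list alone), median log2 fold change 2.37, camera adjusted p = 0.0413, or 0.619 with an estimated correlation, and the call was lost without Control 0D replicate 2 or 4 or DDC 0D replicate 6 or 8 (adjusted p from 0.0528 to 0.0594). For sinusoidal endothelial genes, 7 of 15 measured genes fell (7 adjusted over the list alone), median log2 fold change -0.29, camera adjusted p = 0.0376, or 0.431 with an estimated correlation, a call lost under the stricter filter and with lane as a term (adjusted p = 0.0518 and 0.0627). Of the alcohol and acetaldehyde metabolism genes, 1 of 13 measured genes rose and 9 fell (1 and 9 adjusted over the list alone), median log2 fold change -0.74, camera adjusted p = 8.35e-04, or 0.136 with an estimated correlation. Hmox1, heme oxygenase, rose (2.42 ± 0.35), while Fech, the ferrochelatase that DDC inhibits, fell (-0.44 ± 0.11) and Alas1, the first enzyme of heme synthesis, stood at 0.69 ± 0.47 (adjusted p = 0.229 by edgeR's quasi-likelihood test).

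Lists that did not pass in DDC 0D against Control 0D included those below. Of the heme genes, 2 of 14 measured genes rose and 5 fell (2 and 7 adjusted over the list alone), median log2 fold change -0.30, camera adjusted p = 0.194, or 0.586 with an estimated correlation. Of the bile transport genes, 3 of 16 measured genes rose and 6 fell (3 and 6 adjusted over the list alone), median log2 fold change 0.01, camera adjusted p = 0.194, or 0.314 with an estimated correlation, where the mean was -0.25 and the test pointed down. The sodium-taurocholate carrier Slc10a1 fell (-2.30 ± 0.20). Of the stress response genes, 3 of 24 measured genes rose and 8 fell (3 and 8 adjusted over the list alone), median log2 fold change -0.43, camera adjusted p = 0.146, or 0.608 with an estimated correlation. Of the circadian clock genes, 7 of 16 measured genes rose and 6 fell (7 and 6 adjusted over the list alone), median log2 fold change 0.52, camera adjusted p = 0.605, or 0.735 with an estimated correlation, where the test pointed down. Of the B and plasma cell genes, 2 of 8 measured genes fell (2 adjusted over the list alone), median log2 fold change -0.87, camera adjusted p = 0.504, or 0.841 with an estimated correlation.

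Other splits of the same libraries into groups of the same sizes were refitted with only the groups compared. There were 35 splits for DDC 0D against Control 0D and 100 drawn for each other comparison. Such refits can call other genes than the fits reported above, as with 101 against 488 genes for DDC+HFD against DDC+Cont. The number of splits limits how small a share can be, and shares were not adjusted over the 12 comparisons. In 9 comparisons only the real split, 1 of those run, gave as many calls, which makes chance an unlikely source of those calls. These were DDC 0D against Control 0D (7333, highest other 8), DDC+Cont against Control 28D (177, highest other 78), EtOH against HFD (2868, highest other 76), DDC+HFD against DDC+Cont (101, highest other 0), DDC+EtOH against DDC+HFD (804, highest other 122), DDC+EtOH against EtOH (243, highest other 34), DDC+HFD against HFD (1376, highest other 285), DDC+EtOH against Control 28D (3256, highest other 1355) and Control 28D against Control 0D (688, highest other 216). For HFD against Control 28D 2 of 100 splits were as large, the real one with 105 and another with 238. The share was under 0.05 but unadjusted, and a split other than the real one gave more calls. Chance was therefore not excluded for this comparison. That other split set replicates 9, 10, 11, 14, 15 and 17 against the rest and so mixed both groups. For the DDC interaction 3 of 100 splits were as large, the real one with 4982 and the highest other with 6114, and the larger ones kept the 0D labels whole or mirrored. Labels were shuffled within each stage, so a split that mixes the 0D groups removes the DDC effect at 0D. These splits therefore do not test whether that effect differed between the stages. For the alcohol interaction the real split gave 0 genes by edgeR (739 at an unadjusted p under 0.05, 4 by DESeq2) and the highest other 1, and since no split can give fewer than 0, the splits say nothing about chance there.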
